A study of Mus musculus with 2 samples.

How the data were processed

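Polyadenylated RNA of the STHdhQ7 and STHdhQ111 lines was sequenced on an Illumina platform from randomly primed cDNA, per the labels' protocols, with a library method that is not described there as marking strand. Reads of a gene and an overlapping antisense gene can then not be told apart. Per the submitters' processing notes, TopHat 1.4.0, Bowtie 0.12.7, Cufflinks 2.0.2, Cuffdiff (version not given in the sources used here) and the mm9 build were used. Options, annotation and scaling are not given in the sources used here.

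The values analysed were a table of 23176 genes. Per the file headers it holds the authors' FPKM of each line, combined over replicates, with their log2 fold change, test statistic, p-value and q-value. No other per-sample values were used. Combining the replicates means that no spread between replicates could be computed, no test of the present work could be run, and leaving out a replicate was not possible. Nothing in the labels says that the replicates came from separate cultures, so the authors' p-values may measure technical spread only. The deposited p-value equalled the two-sided normal tail of the deposited statistic to within 2.7e-06, and the deposited q-value equalled the Benjamini-Hochberg adjustment over tested genes to within 2.2e-06. The log2 fold change divided by the statistic therefore gives the standard error that the authors' deposited table implies. The table gives 12740 genes the status OK (tested), 10268 NOTEST, 143 LOWDATA, 24 FAIL and 1 HIDATA. Only tested genes entered the comparisons. Of these, 93 had 1 line listed at 0 and carry no fold change. A listed q of 0 is below the precision of the table.

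The depth per line is unknown. Among 1276 genes between 0.0001 and 0.05 FPKM in both lines, no ratio of the lines was common (the fullest bin of 0.1 log2 units held 5.02%), so relative depth could not be recovered from the low FPKM values. FPKM summed to 426021 in STHdhQ7 and 427714 in STHdhQ111, and the 10 most abundant genes held 7.39% and 6.44% of the sums. Locus starts were read as 0-based, since end minus start equalled the RefSeq gene length (GRCm38, used for lengths and names only) for 7132 of 20606 matched symbols, against 453 with 1 added, and were raised by 1.

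Before the data were examined, 26 gene lists, the threshold of q of 0.05 or less and the rule for naming genes were fixed. The rule takes Htt, Sox2, Pax6 and Nes in any case. It takes the 12 called genes with the largest log2 fold change in each direction at 1 FPKM or more in both lines, and the 8 called genes in each direction with under 0.1 FPKM in 1 line and the highest FPKM in the other. It takes up to 5 called and 2 uncalled members per list, and it leaves provisional symbols and small RNAs unnamed. Some genes the rule gives were left out for length, 1 is not reported here, and where a list had 5 or fewer genes called in 1 direction all of them were named. Those of them that the rule does not give, Ifit3, the untested neuronal and striatal genes and the genes named only in the closing section were chosen after their values were seen.

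Lists with at least 4 tested members were described by the median log2 ratio of (FPKM + 0.5), STHdhQ111 over STHdhQ7, a scale that understates changes of low genes. Its percentile was taken among 10000 random lists of the same size matched on 20 bins of mean FPKM. A list was said to stand apart in the outer 2.5% on either side. This describes these samples and is not a p-value. Calls were also counted after Benjamini-Hochberg adjustment of the deposited p-values over the list alone. Chromosomes were treated in the same way over genes with a mean of 1 FPKM or more, and windows of 25 such neighbouring genes were compared with 1000 shuffles of gene order. Words of 36 bases of the interferon genes were searched in the GENCODE M21 transcripts, on the transcripts' own strand.

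Alternatives covered the threshold, adjustment, filter, fold minimum, scaling, pseudocount, bins and summary of lists. The steps were tested on simulated data. Of 200 simulated lists of 20 genes without a shift, 4.5% stood apart, and of 200 shifted by 0.5 on the log2 scale 97% did (12647 genes). These ratios were independent normal draws with the implied errors, and the members were drawn at random. Real ratios spread wider, with 13.5% of tested genes called, and list members can be regulated together. The simulated rates therefore may not hold for the real lists. With the implied errors, 12% of simulated genes changed by 1 on the log2 scale were called and 40% of those changed by 1.5. The shares were 64% for a change of 2 and 90% for a change of 3, 50 genes each. Only 200 of the 12647 simulated genes were changed, a far smaller share than the 13.5% called in the real table. The Benjamini-Hochberg adjustment is stricter when fewer genes change, so these shares are likely too low for the real table. All of 50 planted blocks were found as the highest window. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.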

Results

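Gene expression was measured by mRNA sequencing in a pair of mouse cell lines derived from the embryonic day 14 striatum, the forebrain region that degenerates in Huntington's disease. The STHdhQ7 line is homozygous for a huntingtin gene (Htt) with the label Q7, and the STHdhQ111 line for the Q111 form, whose longer CAG tract encodes an expanded polyglutamine stretch. Both lines were kept at 33 °C and moved to 39 °C for 2 days to stop cell division. The titles of the 2 samples name 3 replicates each, and the values used here are 1 combined value per line. The depth of the libraries is unknown, because the values are FPKM (fragments scaled to transcript length and to mapped fragments) and the low values showed no common step. All FPKM given below are the authors' combined values, with no replicate spread of their own. All coordinates are those of the table's loci on the mm9 mouse build, and a locus can span overlapping genes.

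The comparison asked which genes differ in expression between cells with expanded and normal huntingtin. It sets 1 line against 1 line, so genotype and the separate history of each line cannot be told apart here. The authors' deposited table held 23176 genes, of which 12740 had a test, and 1723 of those had a q of 0.05 or less and are referred to as called. Of the called genes, 809 were higher and 914 were lower in STHdhQ111, so 47.0% were higher (95% Wilson interval 44.6% to 49.3%, counting error only). After recentring by the median of expressed genes (-0.05) the share was 49.8%, outside that interval. Changes of at least 10-fold were found in 268 called genes that were higher and 290 that were lower, genes listed at 0 in 1 line included. The standard error of the log2 fold change that the authors' deposited table implies had a median of 0.44 and a minimum of 0.37. The smallest called change in the authors' deposited table was 2.03-fold.

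Htt itself was not called. It lies on chromosome 5 at 35104389 to 35255170 and was listed at 3.91 FPKM in STHdhQ7 and 2.83 FPKM in STHdhQ111. The log2 fold change of Htt in the authors' deposited table was -0.47 with an implied standard error of 0.39 (the authors' q = 0.663). Each line is homozygous, so each value comes from 1 form of Htt.

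**Figure D1:**
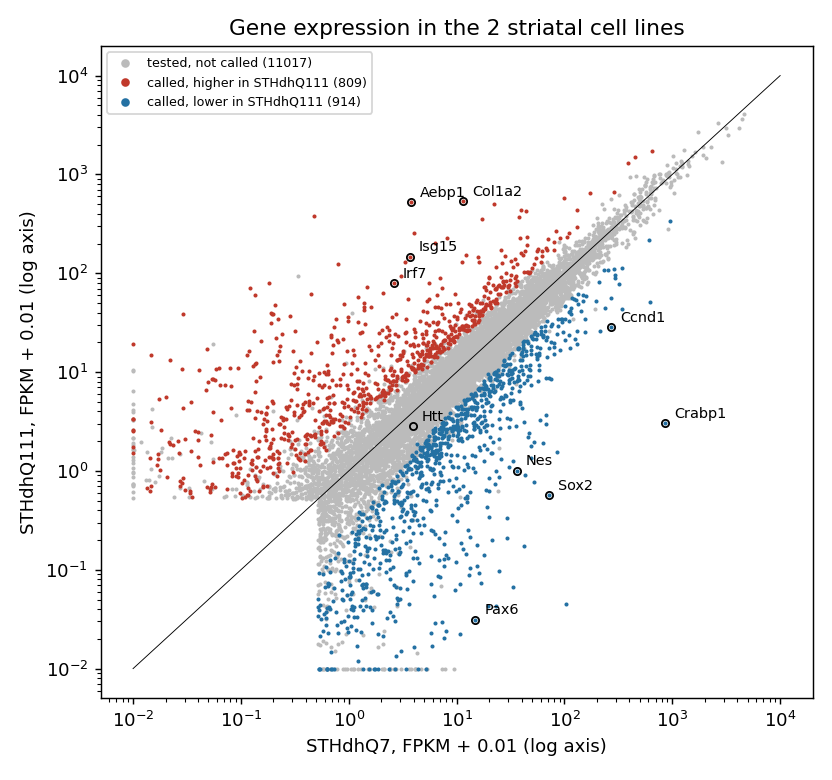
Each point is 1 of the tested genes, with its FPKM in STHdhQ7 on the horizontal axis and in STHdhQ111 on the vertical axis, both log axes with 0.01 added and the line marking equality. Red points are the 809 called genes higher in STHdhQ111, blue points the 914 called genes lower in it, and grey points were not called. Crabp1, Sox2 and Pax6 lie far below the line, Aebp1, Irf7 and Isg15 far above it, and Htt close to it.

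Transcription factors and structural genes of neural progenitors were among the steepest losses in STHdhQ111. Sox2, a factor that maintains neural stem cells (chromosome 3, 34459303 to 34576915), fell from 72.0 to 0.561 FPKM, 128-fold. The log2 fold change of Sox2 in the authors' deposited table was -7.00 with an implied standard error of 0.72 and a q listed as 0. Pax6, a regulator of forebrain patterning (chromosome 2, 105376237 to 105537521), fell from 14.9 to 0.0213 FPKM, and its log2 fold change in the authors' deposited table was -9.45 with an implied standard error of 2.15 (the authors' q = 0.000224). The size of these falls rests on values near 0 in STHdhQ111, and with a pseudocount of 1 the log2 ratio was -3.96 for Pax6 and -5.55 for Sox2. Nes, which encodes the progenitor intermediate filament nestin (chromosome 3, 87775015 to 87784373), fell from 35.99 to 0.999 FPKM. Its log2 fold change in the authors' deposited table was -5.17 with an implied standard error of 0.49, and its log2 ratio with a pseudocount of 1 was -4.21. Lhx2 fell from 59.0 to 3.28 FPKM and Emx2 from 18.8 to 4.89 FPKM. Of the 14 tested members of the list of neural progenitor and forebrain patterning factors, 6 were called lower, these 5 among them, 2 were called higher (Dlx2 and Sox9) and 6 were not called, and 9 passed when adjusted over the list alone. Vimentin (Vim), an intermediate filament protein, was listed at 3303 and 2483 FPKM and was not called. The median log2 ratio of the list was -0.50, at percentile 0.41 among random lists matched on expression. In the same comparison the mesenchymal, fibroblast and mural markers had a median of 0.50, above all 10000 matched random lists, with 6 of 22 called higher, 2 called lower and 14 not called.

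Some neuronal genes were also called, but only 10 of the 30 listed pan-neuronal genes had a test. Those without one included Rbfox3 (0.00738 FPKM in STHdhQ7 and 0.0318 FPKM in STHdhQ111), Snap25 (0.0301 and 0.0369 FPKM) and Dcx (0.0102 and 0.0238 FPKM). Of the 10 tested pan-neuronal genes, 4 were called lower (Stmn2, Ncam1, L1cam and Uchl1), 1 was called higher (Slc17a7) and 5 were not called, and 5 passed when adjusted over the list alone. Stmn2, a microtubule regulator of growing axons, fell from 33.5 to 0.0563 FPKM. The median log2 ratio of the list was -0.77, at percentile 0.58. Of the 28 listed genes of striatal medium spiny neurons, only 8 had a test. Drd1 (0 FPKM in both lines), Ppp1r1b (0.136 and 0.0698 FPKM) and Bcl11b (0.0648 and 0.0610 FPKM) had none. Among the 8 tested, Pde1b, Rgs9 and Meis2 were called lower, Foxp1 was called higher and 4 were not called. When adjusted over the list alone, 4 passed. Pde1b, a phosphodiesterase, fell from 11.7 to 1.01 FPKM, while Foxp1 rose from 9.35 to 22.4 FPKM. The median of this list was -0.57 at percentile 3.25, which does not stand apart.

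The interferon response list was higher in STHdhQ111 almost throughout. Of its 32 tested members, 31 were called higher and 31 passed when adjusted over the list alone. The remaining member, Ifit2, was listed at 15.4 and 23.6 FPKM. The median log2 ratio was 2.69, above all 10000 matched random lists. Irf7, the transcription factor that amplifies type I interferon production (chromosome 7, 148449082 to 148452323), rose from 2.62 to 79.7 FPKM, and its log2 fold change in the authors' deposited table was 4.93 with an implied standard error of 0.55. Isg15, a ubiquitin-like modifier (chromosome 4, 155573533 to 155574927), rose from 3.65 to 146.9 FPKM, 40.2-fold. The 2'-5' oligoadenylate synthetase-like gene Oasl2 rose from 0.198 to 48.0 FPKM and Oas1a from 0.209 to 34.7 FPKM. Oasl1 was listed at 0 in STHdhQ7 and at 2.60 FPKM in STHdhQ111, so no fold is given. Some of these genes have near-identical relatives, and only 34.3% of the 36-base words of Oas1a and 41.5% of those of Ifit3 occurred in no other gene's transcripts, which makes their separate values uncertain.

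**Figure D2:**
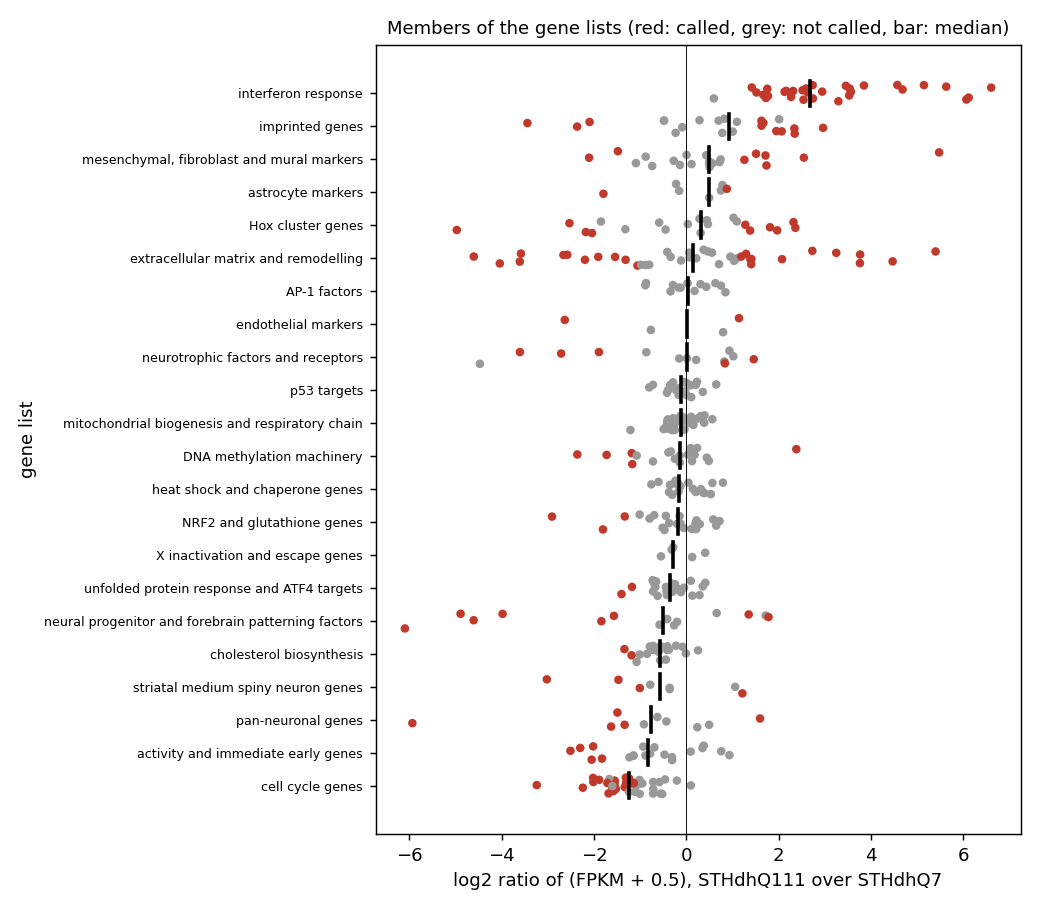
Each point is a tested member of a gene list, placed by its log2 ratio of (FPKM + 0.5), STHdhQ111 over STHdhQ7, with called members in red, others in grey and a black bar at the list's median. The 22 lists with at least 4 tested members are ordered by median, from cell cycle genes at -1.24 to the interferon response at 2.69.

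Cell cycle genes were lower in STHdhQ111, although the shift to 39 °C was meant to stop division in both lines. Of the 38 tested members 19 were called lower and none was called higher, and 25 passed when adjusted over the list alone, all of them lower. The median log2 ratio was -1.24, below all 10000 matched random lists. Ccnd1, the cyclin D1 that drives entry into S phase (chromosome 7, 152115836 to 152125830), fell from 272.4 to 28.4 FPKM, and its log2 fold change in the authors' deposited table was -3.26 with an implied standard error of 0.41. The replication helicase genes Mcm3 and Mcm5 fell from 101.5 to 21.1 FPKM and from 72.0 to 17.4 FPKM. Ccnd3 was listed at 71.4 and 62.0 FPKM and was not called. None of the 20 tested genes of the p53 target list was called. The list also holds the p53 gene Trp53 itself and Cdkn2a, which act upstream of the targets. The arrest genes Cdkn1a and Cdkn2a were abundant in both lines. Cdkn1a was listed at 1138 FPKM in STHdhQ7 and 934 FPKM in STHdhQ111. The p53 list's median was -0.10 at percentile 21.4, and none of it passed when adjusted over the list alone. Random lists matched to it held 1.81 called genes on average (percentile 7.4 for the calls), so the lack of calls did not stand apart.

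Activity and immediate early genes held called members in 1 direction. In this list 5 of 20 tested members were called lower and none was called higher, and 8 passed when adjusted over the list alone. The 5 called lower were Spry4, Etv4, Egr2, Etv5 and Spred1, most of which are known as targets or inhibitors of ERK signalling. Spry4 fell from 2.41 to 0.0927 FPKM and Etv4 from 19.1 to 2.94 FPKM. The immediate early genes Egr1 (53.1 and 38.2 FPKM) and Dusp1 (38.3 and 41.0 FPKM) were not called. The list's median log2 ratio was -0.83, below all 10000 matched random lists. The number of calls did not stand apart from those lists (2.65 on average, percentile 92.6). No AP-1 factor of the 13 tested was called, and none passed when adjusted over the list alone (median 0.03, percentile 66.6). Random lists matched to the AP-1 list held 1.46 called genes on average (percentile 10.8 for the calls), so the lack of calls did not stand apart. Among the 13 tested neurotrophic factors and receptors, Igf1, Fgf2 and Gfra1 were called lower and Lif and Ret higher, 5 passed when adjusted over the list alone, and the median was 0.02 at percentile 68.9. Igf1 fell from 6.11 to 0.0440 FPKM. Bdnf, a trophic factor of striatal neurons, was listed at 12.1 and 23.6 FPKM and was not called.

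The mesenchymal and matrix genes changed in both directions. Of 22 tested mesenchymal, fibroblast and mural markers, 6 were called higher and 2 lower (Postn and S100a4), 8 passed when adjusted over the list alone, and the median log2 ratio of 0.50 lay above all 10000 matched random lists. Col1a2, a chain of type I collagen (chromosome 6, 4455697 to 4491543), rose from 11.5 to 532.6 FPKM. Its log2 fold change in the authors' deposited table was 5.54 with an implied standard error of 0.47. Col1a1 rose from 451.9 to 1487 FPKM, whereas periostin (Postn) fell from 7.93 to 1.46 FPKM. The 40 tested genes of extracellular matrix and remodelling split into 12 called higher and 11 called lower, and 26 passed when adjusted over the list alone. Fibrillin 2 (Fbn2) rose from 0.122 to 25.8 FPKM and the laminin chain Lama4 from 0.129 to 8.07 FPKM. The matrix metalloproteinase Mmp10 fell from 7.94 to 0.0139 FPKM and the collagen Col11a1 from 6.86 to 0.115 FPKM. The matrix list's median of 0.15 stood at percentile 98.2, but its mean of 0.13 stood at percentile 82.1.

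Called genes at 1 FPKM or more in both lines were ranked, with provisional symbols and small RNAs left out. Among them the steepest gain was in Aebp1, which encodes a secreted matrix-associated protein (chromosome 11, 5761869 to 5778259). It rose from 3.74 to 526.5 FPKM, with a log2 fold change in the authors' deposited table of 7.14 and an implied standard error of 0.71. The galectin Lgals9 rose from 4.01 to 254.2 FPKM, the prostaglandin E synthase Ptges from 1.38 to 50.3 FPKM, the pentraxin Ptx3 from 3.28 to 130.9 FPKM and the growth factor binding protein Igfbp2 from 6.25 to 204.2 FPKM. Among the same ranked genes the steepest loss was in Crabp1, a cytoplasmic retinoic acid binding protein (chromosome 9, 54612615 to 54620916). It fell from 856.2 to 3.045 FPKM, with a log2 fold change in the authors' deposited table of -8.14 and an implied standard error of 0.62. The water channels Aqp5 and Aqp1 fell from 49.3 to 1.34 FPKM and from 33.6 to 1.25 FPKM, the integrin Itga7 from 30.4 to 1.09 FPKM and the EGF receptor ligand Areg from 47.0 to 2.40 FPKM.

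**Figure D3:**
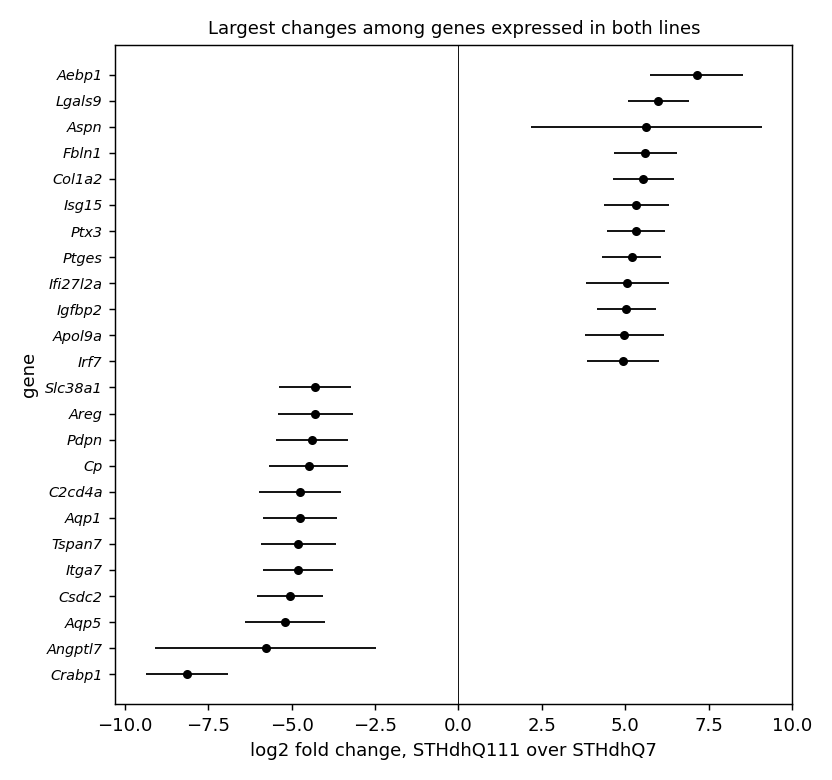
Points give the log2 fold change of STHdhQ111 over STHdhQ7 from the authors' deposited table. The genes are the 12 steepest rises and 12 steepest falls among called genes at 1 FPKM or more in both lines. Provisional symbols and small RNAs were left out of the ranking. Bars are 95% normal intervals from the standard error that the table implies, and none crosses 0. Aspn and Angptl7 have the widest bars.

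Other called genes were near absent in 1 line. There were 99 with under 0.1 FPKM in STHdhQ7 and 162 with under 0.1 FPKM in STHdhQ111. The adhesion receptor Selp was listed at 0.0190 FPKM in STHdhQ7 and 38.7 FPKM in STHdhQ111, the aminopeptidase Enpep at 0.00451 and 15.0 FPKM, and the sodium channel Scn3a at 0.0121 and 13.3 FPKM. The X-linked gene Xlr was listed at 0 in STHdhQ7 and at 19.1 FPKM in STHdhQ111. In the other direction, the adhesion molecule Cadm1 went from 103.2 to 0.0354 FPKM, Rgs16 from 24.9 to 0.0863 FPKM, the Wnt inhibitor Dkk2 from 19.4 to 0.0333 FPKM, and the heart and motor neuron factor Tbx20 from 15.98 to 0.0818 FPKM.

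The title of the series concerns DNA methylation, and genes tied to it were mixed. Of 19 tested genes of the DNA methylation machinery, 4 were called lower (Dnmt1, Uhrf1, Tet1 and Hells) and 1 higher (Gadd45g), and 6 passed when adjusted over the list alone. The maintenance methyltransferase Dnmt1 fell from 50.4 to 21.9 FPKM and its partner Uhrf1 from 44.7 to 8.30 FPKM. The dioxygenase Tet1 fell from 1.22 to 0.266 FPKM, and Gadd45g rose from 28.3 to 149.9 FPKM. The list's median of -0.14 was at percentile 24.8. Of the 22 tested imprinted genes, 8 were called higher, 3 lower (Peg10, Snrpn and Ndn) and 11 were not called, 12 passed when adjusted over the list alone, and the median of 0.92 lay above all 10000 matched random lists. H19 rose from 0.161 to 2.06 FPKM, Meg3 from 0.0960 to 1.34 FPKM and Mest from 2.65 to 24.1 FPKM, whereas Peg10 fell from 35.8 to 2.85 FPKM. In the Hox clusters, 6 of 21 tested genes were called higher and 4 lower (Hoxc10, Hoxb13, Hoxc8 and Hoxc6), and 14 passed when adjusted over the list alone. Hoxa2 rose from 0.0205 to 2.10 FPKM, and Hoxb13 fell from 43.3 to 0.897 FPKM. The Hox list's median of 0.31 stood at percentile 99.0, while its mean had the opposite sign (-0.05, percentile 60.0). Of the germline genes only Tdrkh and Brdt had a test, neither was called, and none passed when adjusted over the list alone.

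Metabolic and stress lists held about as many called genes as matched random lists, or fewer. The random lists held on average 2.21 for cholesterol biosynthesis, 2.41 for the unfolded protein response and 2.31 for NRF2 genes. They held 3.39 for mitochondrial genes (percentile 1.44 for the calls) and 1.88 for heat shock genes (percentile 6.6). In cholesterol biosynthesis 20 of 21 tested genes had a ratio below 0 and the median of -0.56 lay below all 10000 matched random lists, although only Hsd17b7 and Idi1 were called and 1 gene passed when adjusted over the list alone. Hsd17b7 fell from 11.4 to 4.22 FPKM. The unfolded protein response and ATF4 target list had a median of -0.36 at percentile 0.07, with Psat1 and Vldlr called lower of 24 tested and 2 passing when adjusted over the list alone. No gene was called, and none passed when adjusted over the list alone, among the 34 tested mitochondrial genes (median -0.11, percentile 16.01) and the 21 heat shock and chaperone genes (median -0.17, percentile 6.54). Of 22 tested NRF2 and glutathione genes, Gsta1, Gsta4 and Gstm2 were called lower, 3 passed when adjusted over the list alone, and the median was -0.17 at percentile 9.47.

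Markers of other cell types did not move together. Of the 12 microglial and leukocyte markers, 10 were under 0.5 FPKM in STHdhQ111, and the median was 0.0223 FPKM. The exceptions, Cd68 and Laptm5, were both called higher and both passed when adjusted over the list alone, with Cd68 rising from 26.5 to 72.4 FPKM and Laptm5 from 0.175 to 1.08 FPKM. Among 4 tested endothelial markers Flt1 was called lower and Tek higher, 3 passed when adjusted over the list alone, and the median was 0.02 at percentile 62.4. Of 7 tested astrocyte markers Sparcl1 was called higher and Aldoc lower, and 2 passed when adjusted over the list alone. The astrocyte median of 0.50 stood at percentile 98.6, but over members with a mean of 1 FPKM or more it was 0.17 at percentile 85.1, and the mean of the list was 0.11 at percentile 73.5. Of 3 tested oligodendrocyte lineage markers Pdgfra was called higher, and 1 passed when adjusted over the list alone. None of the 4 Y-linked genes had a test. None of the 5 tested X-linked genes of inactivation and escape was called or passed when adjusted over the list alone (median -0.28, percentile 15.8). Random lists matched to these genes held 0.50 called genes on average, so the lack of calls did not stand apart.

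Changes were spread over the genome. The median log2 ratio of expressed genes per chromosome ran from -0.25 on chromosome 1 to 0.18 on chromosome 14, and 15 of the 20 chromosomes lay outside the central 95% of matched random gene sets. In windows of 25 neighbouring expressed genes, the highest absolute median was 1.19, on chromosome 11 from 74989445 to 76212643, where 13 genes were called higher and 1 was called lower.

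**Figure D4:**
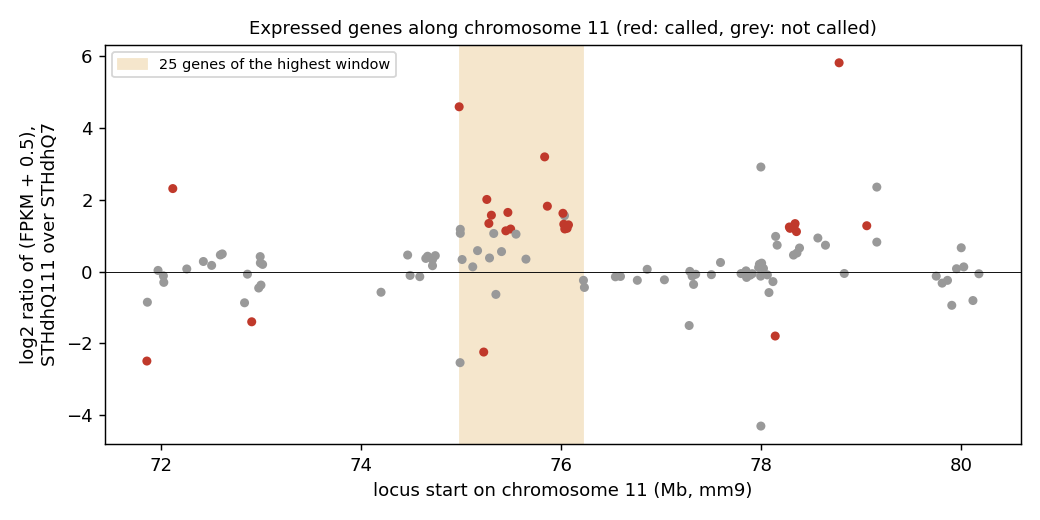
Each point is an expressed gene at its locus start on chromosome 11 (Mb, mm9), with its log2 ratio of (FPKM + 0.5), STHdhQ111 over STHdhQ7, on the vertical axis, and called genes in red. The shaded stretch holds the 25 genes of the window with the highest median, 23 of which lie above 0.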

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

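The tests of leukocytes, of the polyglutamine tract and of dilution below were chosen after the results were seen, and the others before. Replicates and differences between contrasts were not tested, as the table holds 1 combined value per line and 1 contrast.

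Genes the comparison left out for lack of a test were searched by a rule set after their values were seen. Of those not tested, it takes genes higher in STHdhQ111 whose deposited p, adjusted over such genes, was 0.05 or less. Of those with the status FAIL, LOWDATA or HIDATA, it takes genes at 10 FPKM or more in STHdhQ111 and at least 2 times their STHdhQ7 value. The rule looked only for rises, so genes lower in STHdhQ111 were not searched. It gave 3 genes. Bai1 was listed at 0.0261 FPKM in STHdhQ7 and 0.501 FPKM in STHdhQ111, and the authors' deposited table gives it a p of 3.04e-07, which is 0.00312 after adjustment over the untested genes. Plec, which encodes plectin, was listed at 63.1 and 138.0 FPKM with a failed test. Rnaset2a was listed at 43.9 and 95.4 FPKM with the status LOWDATA, and the reason for that status was not examined.

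The first pattern weighed is the spread of called genes over the genome. The median log2 ratios of the chromosomes ran from -0.25 to 0.18, small beside the smallest called log2 fold change, 1.02 in size. Medians this small argue against whole-chromosome copy number as the main cause. Subtracting them could remove few calls, so it adds little that 92.7% of the called genes were still called afterwards. The share called within 10 Mb of Htt was 0.978 times that elsewhere (95% Wilson bounds 0.614 to 1.51, 16 of 121 genes). It lay below the 2 times set beforehand as the mark of alleles carried along with Htt, so no excess of calls near Htt was seen. A few such alleles, or one acting on genes elsewhere, need not raise this share, so the test cannot exclude them. Windows of 25 genes had medians beyond 0.4 in 438 of 11051 cases, against at most 81 in 100 shuffles, yet 87.6% of the called genes were still called after the median of their neighbours was subtracted. Neighbouring genes thus shifted together more often than in shuffles, but such shifts may account for only a part of the calls.

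The second pattern is the rise of interferon response genes. Leukocytes in the STHdhQ111 cultures would bring their abundant transcripts, yet the leukocyte list had a median of 0.0223 FPKM there, with Ptprc at 0.00334 FPKM, although Cd68 (72.4 FPKM) was abundant. Reads shared between related genes would leave unique genes unmoved, yet 20 of the 21 tested members with at least 95% unique 36-base words were called higher, and the 20 with a fold change, all but Oasl1, had a median log2 fold change of 2.87 from the authors' deposited table. The expanded polyglutamine tract itself stays open, because there was 1 independent line per genotype, so that the tract cannot be told apart from any other difference between the lines.

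The third pattern is the loss of neural progenitor genes. Dilution of STHdhQ7-like cells by others giving a minority of the RNA could lower a gene by at most 1 on the log2 scale. In 5 of 14 tested members (Sox2, Pax6, Nes, Lhx2 and Emx2) the 95% normal interval of the log2 fold change was wholly below -1. The intervals are from the authors' deposited table. Dilution by a minority of the RNA is thus too small for these 5 genes. RNA per cell is unknown, so a minority of cells rich in RNA was not excluded. The 5 genes are also among the steep falls that drew attention to the pattern, so the outcome was known beforehand. The count of members below -1 was the last of 3 forms of the test, all set after the values were seen. The earlier forms used the median of the 6 called lower members (-4.67) and that of all 10 lower members (-1.78, computed from the FPKM). The mesenchymal, fibroblast and mural markers had a median log2 ratio of 0.50, with 6 of 22 called higher, 2 called lower and 14 not called, and a larger share of other cells, or cells of another kind throughout, was not tested. The expanded polyglutamine tract itself again cannot be told apart from other differences, with 1 independent line per genotype.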

How the results depend on the processing

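No paired analysis was possible because the table holds 1 combined value per line, and for the same reason no replicate could be left out. The count of called genes was 1723 and ran from 1224 at a q of 0.01 or less to 1723, within 1.5 times under each of the 6 alternatives. Recomputing the adjustment, a fold of at least 2 and 1 row per symbol changed nothing, since every called gene already exceeded a 2-fold change and no symbol repeated. The share of called genes that were higher in STHdhQ111 moved from 47.0% to 49.8% when fold changes were recentred on expressed genes, by their median of -0.05, which shifts each gene towards higher by construction, and 1665 of the called genes were still called. Of 22 lists 12 stood apart, and 10 to 12 did under the alternatives. With the mean in place of the median the Hox list reversed to -0.053, and the cause was not tested. With the mean the astrocyte and matrix lists no longer stood apart while the NRF2 list did, and the astrocyte list also failed over genes with a mean of 1 FPKM or more. Including genes with several symbols moved nothing, since there were none. List calls, counted once per list, were 148, with 167 when adjusted over the list alone and 125 at a q of 0.01 or less. For the 43 named genes tested, another pseudocount cannot change direction, and recentring by -0.05 is smaller than any of their changes. Their direction was therefore not put to a test. With a pseudocount of 1, 28 of these genes moved by more than their implied error. Chromosomes standing apart numbered 15, and 14 with called genes left out. Chosen after the data were seen, windows of 15 genes gave 1.21 over the chromosome 11 block, but the highest window was then in the histone cluster of chromosome 13 (1.23). Depth is unknown, and each called change with a fold was above 2-fold.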

Other observations

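The gene families below were grouped by symbol and chosen after their values were seen, among 212 families with at least 8 tested members, and the windows were chosen in the same way. Of 11 tested Wnt ligands, 6 were called higher in STHdhQ111, 1 lower and 4 were not called, with a median log2 ratio of 1.51. Wnt10a rose from 5.51 to 54.7 FPKM, Wnt16 from 2.44 to 14.8 FPKM and Wnt5a from 1.08 to 5.24 FPKM, and Wnt10b was listed at 0 and 3.36 FPKM, whereas Wnt7a fell from 6.08 to 0.236 FPKM. Receptors of the tumour necrosis factor family showed 7 of 13 called higher and none lower, with a median of 1.13. Tnfrsf11b, the decoy receptor osteoprotegerin, rose from 0.747 to 34.4 FPKM, and Tnfrsf18 from 2.03 to 26.8 FPKM. Histone genes had a median of 1.11 over 60 tested, with 11 called higher and none lower, but matched random lists held 10.7 called genes on average, so the number of calls did not stand apart. The kinesin family had a median of -0.56 with 8 of 30 called lower, and this number did not stand apart from matched random lists either (4.69 on average, percentile 94.3). Most histone transcripts lack a poly(A) tail and have near-identical copies, so their values are uncertain. Each of these family medians is far from 0 beside the shift of -0.05 that recentring removes.

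A stretch of chromosome 11 (mm9, 74989445 to 76212643) was higher in STHdhQ111 in 23 of its 25 expressed genes. Prpf8, a core splicing factor, rose from 55.8 to 167.1 FPKM, Myo1c from 70.2 to 221.4 FPKM, Vps53 from 18.6 to 67.0 FPKM and Crk from 34.9 to 80.2 FPKM. The last gene of the stretch, Nxn, rose from 68.9 to 170.8 FPKM, while its neighbours Timm22 (13.5 and 11.3 FPKM) and Abr (23.5 and 17.2 FPKM) were not called. The 25 genes before the stretch had a median of 0.20 and the 25 after it a median of -0.10. None of 1000 shuffles of gene order gave a window median as high as 1.19, the highest being 0.916. Of the 23 higher genes, 21 had a locus overlapping no other gene of the table, and their median was 1.19. DNA counts of the stretch were not analysed here.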
